A study of Dahlia pinnata with 6 samples.

How the data were processed

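Small RNA was sequenced from petals of the bicolor dahlia cultivar Yuino, whose petals carry a pigmented red part and an unpigmented white part. The parts were dissected from each other, total RNA was extracted with Trizol and libraries were made with a NEBNext small RNA kit, per the labels' protocols. There were 3 libraries from red tissue and 3 from white tissue, grouped by the sample titles. The labels do not say whether the libraries of a part came from separate plants, so p-values measure the spread between these libraries, which may be in part technical.

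The authors deposited a table of counts, whole numbers of small RNA reads per row, with no normalisation. Its 47083 rows were 46967 contigs of a Trinity transcript assembly, from 27530 Trinity genes (groups of isoforms), and 116 rows with microRNA names. Reads were trimmed with cutadapt and aligned with Bowtie2, as far as the submitters' processing notes name tools; versions, settings and the read lengths counted were not given in the sources used here. How reads that match several isoforms were assigned was likewise not given in the sources used here. The contigs carried no gene names in the table, and no sequence or annotation of them was used here. MicroRNA names had at most 6 characters, so a longer family number could have been shortened and joined with another family. Every row had at least 1 read in red replicate 1, while each other library had between 11093 and 12808 rows at 0. Contigs without a read in red replicate 1 were therefore not analysed here, and low counts in that library are biased upward.

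The column totals were 3662222, 3515595 and 3277753 reads for red replicates 1, 2 and 3 and 3512161, 3369234 and 3404769 reads for white replicates 1, 2 and 3. These are totals of the tabulated reads, not of the sequenced libraries. They were deep enough to test 7001 rows (6967 contigs and 34 microRNAs) that passed edgeR's filter on low counts with its minimum count of 10. Of the tested rows, 17 had under 3 reads in red replicate 1.

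White was compared with red by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, robust dispersion and all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the tested rows, with a threshold of 0.05. Normalised counts are CPM of the tested rows after TMM, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Lists of microRNAs were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Measures with 1 value per library were compared by two-sided exact permutation tests (scipy 1.17.1), which cannot give a p below 0.1 for 3 libraries against 3. On counts simulated for the white against red comparison over 7001 rows, with 200 rows changed, the edgeR test recovered 27.6% of 2-fold and 79.4% of 4-fold changes, and 1.8% of its calls were false. The simulated libraries were drawn independently, without the correlation of same-numbered libraries described below, so these rates may not carry over to the data. The lowest chi-square per degree of freedom between libraries of a group was 4.82, so no pair of libraries agreed within sampling noise.

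Red and white libraries share the replicate numbers 1 to 3 in their titles. After group means were removed, log2 values (prior count 2) of same-numbered libraries correlated across rows at 0.20, 0.29 and 0.20 for replicates 1, 2 and 3. All lay above the limit of 0.1 set for treating the numbers as pairs. The other pairings lay between -0.19 and 0.01. Removing the mean of 3 libraries pushes them down when same-numbered libraries correlate positively, so this contrast is in part built in. The pairing rests on these numbers and correlations, since the labels do not say that a number marks a shared plant or day. The main fit was planned without pairs, and the fit with the replicate number as a block is given where it changed a result.

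Tests and alternatives were fixed before the data were examined, as was the rule for what is named: the largest rises and falls among calls whose libraries did not overlap, the 10 most abundant rows, and called microRNAs (at most 5). As the table gives no annotation of contigs, at most 2 contigs that rose, 2 that fell and the 2 most abundant are named, 1 per Trinity gene. Other microRNAs were named after their values were seen. The list of 27 plant microRNA families, the list of 13 insect families and the let-7 names were written after the table was seen. Alternatives were scaling by library totals, DESeq2 (1.42.0), no filter or a stricter filter, a 2-fold minimum, the replicate block and each library left out. Added after seeing the data were isoforms summed to Trinity genes, microRNA rows left out, scaling to the microRNA total, the 3 most abundant contigs left out, and a filter that ignores red replicate 1. Planned comparisons of chalcone synthase, the flavonoid pathway, sources of phased and trans-acting siRNAs, the other contig lists and read length classes were not analysed here, because they need contig annotation or read lengths.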

Results

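Small RNAs were counted in the red, pigmented part and the white, unpigmented part of bicolor dahlia petals, with 3 libraries of each. The study asked whether flavonoid compounds, the pigment family present in the red part, hold back the production of 21-nt siRNAs by DCL4 as a whole. DCL4 is the Dicer-like enzyme that cuts double-stranded RNA into siRNAs of that length in plants. Tabulated reads per library ranged from 3277753 to 3662222. The reads were assigned to transcript contigs of a Trinity assembly, which carry no gene names, or to microRNA names.

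White tissue held far more small RNA of a few contigs than red tissue did. The 3 contigs with the largest rise took 0.092% ± 0.061 (SD, n = 3) of the reads in red and 9.45% ± 0.89 (SD, n = 3) in white. The other 34 contigs that rose in white took 0.598% ± 0.075 in red and 1.29% ± 0.30 in white (SD, n = 3 each). These contigs were picked by the test itself as the largest rises, so their share is given as a size and not tested again. Of the 7001 tested rows, 49.1% had a higher mean in white, and the value ranged from 48.8% to 52.0% over the 9 pairs of a red and a white library. The median log2 fold change of all tested rows was -0.01, a balance that TMM scaling largely sets. It was -0.17 with scaling by library totals, where 34.7% of rows were higher in white, and 0.18 with scaling to the microRNA total, where 67.8% were, so the size and sign of a shift common to all contigs depended on the scaling. Both scalings are themselves moved by changed rows. All contigs that rose in white took 0.69% of the reads in red and 10.7% in white, which lowers other rows under library totals. Without miR159 and miR166, both lower in white, microRNA names took 2.64% ± 0.22 of the reads in red and 2.49% ± 0.13 in white (SD, n = 3 each). Scaling to the microRNA total thus rests in large part on those 2 rows. Total tabulated counts depend on how deep each library was sequenced, so they cannot show whether small RNA production as a whole differs. They were 3485190 ± 194030 in red and 3428721 ± 74413 in white (SD, n = 3 each), a difference within the spread between libraries (exact permutation p = 0.6). Without the 10 most abundant rows they were 1634112 ± 113500 in red and 1415585 ± 164973 in white, with each red library above each white one (exact permutation p = 0.1, the smallest possible), but the rows left out include the 3 contigs with the largest rise, whose removal by itself lowers the white totals. Contig reads per microRNA read were 20.1 ± 1.1 in red and 25.7 ± 0.8 in white (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, adjusted 0.2 over 4 library measures). Without the contigs that rose in white, this ratio was 19.9 ± 1.1 in red and 22.8 ± 0.4 in white (exact permutation p = 0.1). Every row is a contig or a microRNA, so this ratio restates the microRNA share of the reads given further on. It is not a separate result, and the 4 library measures hold both. The lower counts of miR166 and miR159 in white, of which only miR166 passed the main test, move the ratio too.

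By edgeR's quasi-likelihood test, 74 rows changed between the parts at an adjusted p under 0.05, of which 37 rose and 37 fell in white. At an unadjusted p under 0.05 there were 878 rows, and in 17.8% of tested rows the red and white libraries did not overlap, against 10% by chance. The risen rows were contigs of 27 Trinity genes, and the fallen rows were 36 contigs of 29 Trinity genes and 1 microRNA. The rises were larger: 10 called contigs rose at least 8-fold and no called row fell that far, with a median log2 fold change of 1.89 among risen and -0.93 among fallen rows. All 3 called rows with under 3 reads in red replicate 1 were rises. TRINITY_DN1637_c0_g1_i1 rose most, from 289.6 ± 229.5 CPM in red to 35990 ± 1176 CPM in white (SD, n = 3 each), a 124-fold ratio of means (log2 fold change 6.96 ± 0.79 SE, edgeR adjusted p = 0.049). The other isoform of the same Trinity gene stood at 348.2 ± 234.2 CPM in red and 41870.5 ± 1475 CPM in white (log2 fold change 6.91 ± 0.66 SE, edgeR adjusted p = 0.027). TRINITY_DN122_c0_g2_i5 rose 89.5-fold, from 274.5 ± 177.1 to 24568 ± 2148 CPM (log2 fold change 6.48 ± 0.61 SE, edgeR adjusted p = 0.023). The red libraries varied widely for these contigs: TRINITY_DN1637_c0_g1_i1 stood at 196.2, 551.1 and 121.6 CPM in red replicates 1 to 3. The steepest fall was that of TRINITY_DN16508_c0_g1_i1, from 223.4 ± 30.6 CPM in red to 37.7 ± 15.1 CPM in white, a 5.92-fold ratio (log2 fold change -2.57 ± 0.27 SE, edgeR adjusted p = 0.0033). TRINITY_DN20552_c0_g1_i1 fell from 485.1 ± 86.6 to 145.3 ± 4.5 CPM, a 3.34-fold ratio (log2 fold change -1.74 ± 0.15 SE, edgeR adjusted p = 1.0e-04).

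With the replicate number as a block, edgeR called 338 rows, 157 higher and 181 lower in white, including 72 of the 74. With scaling by library totals the calls split into 45 higher and 109 lower, and with scaling to the microRNA total into 117 higher and 19 lower. Leaving out red replicate 1 left 46 calls, leaving out red replicate 2 gave 176 and leaving out white replicate 3 left 35. The risen calls numbered 23 without white replicate 2, and the fallen calls 23 without white replicate 1. TRINITY_DN1637_c0_g1_i1 had log2 fold changes from 6.59 to 7.82 with 1 library left out, the highest without red replicate 2, but its call was lost with the block (adjusted p = 0.081), with no filter on low counts (adjusted p = 0.13), with the most abundant contigs left out (adjusted p = 0.052) and without red replicate 1 or 3 or any 1 of the white libraries (adjusted p from 0.058 to 0.21). The call of TRINITY_DN122_c0_g2_i5 held with the block (adjusted p = 7.7e-04) and was lost with no filter (adjusted p = 0.082) and without red replicate 1 or any 1 of the white libraries (adjusted p from 0.084 to 0.15), at log2 fold changes of 6.31 or more; without red replicate 2 its log2 fold change was 7.14. With isoforms summed, the Trinity gene of TRINITY_DN1637_c0_g1_i1 had a log2 fold change of 6.90 ± 0.73 SE (edgeR adjusted p = 0.051) and that of TRINITY_DN122_c0_g2_i5 one of 3.42 ± 0.13 SE (edgeR adjusted p = 6.6e-10). Of 15 alternatives, the call of TRINITY_DN1637_c0_g1_i1 held in 7 and that of TRINITY_DN122_c0_g2_i5 in 10. DESeq2 gave them adjusted p-values of 2.4e-23 and 1.3e-83. Both falls of the named contigs passed under every alternative run on them.

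**Figure D1:**
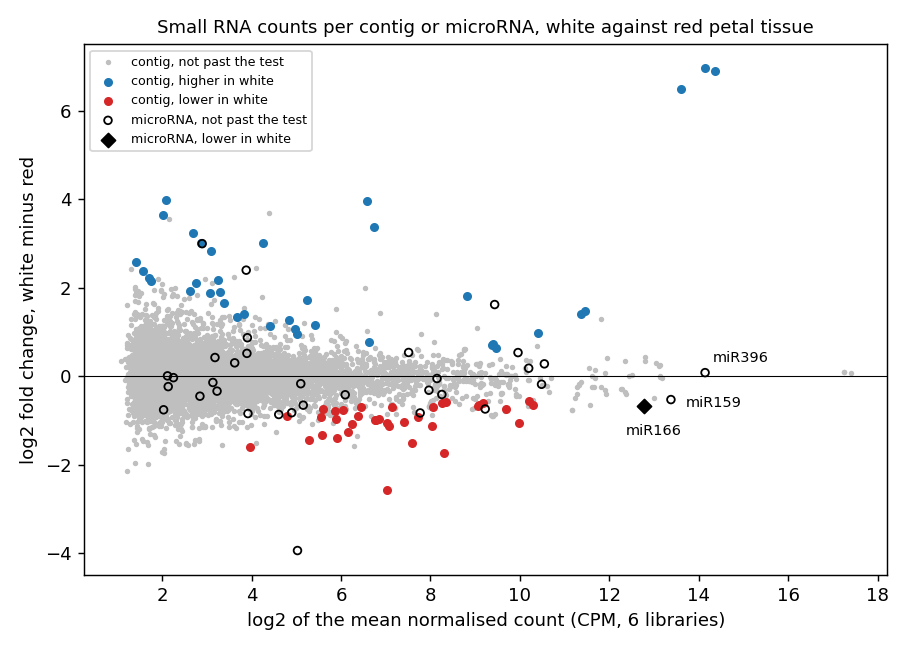
Each point is a contig or microRNA, with the log2 of its mean normalised count on the x axis and the log2 fold change (white minus red, edgeR, 3 libraries per group) on the y axis. Coloured points passed an adjusted p of 0.05, and the 3 contigs at log2 fold changes between 6.48 and 6.96 lie apart from all other rows.

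Among the abundant microRNAs, miR166 and miR159 had lower counts in white. miR166, which directs cleavage of class III HD-ZIP transcripts of organ polarity, was the only microRNA that passed over all tested rows. It fell from 8550 ± 1028 CPM in red to 5366 ± 240.1 CPM in white (SD, n = 3 each; log2 fold change -0.67 ± 0.12 SE, edgeR adjusted p = 0.022). miR159, which targets GAMYB-like transcription factors, stood at 12547 ± 596.3 CPM in red and 8701 ± 1045 CPM in white (log2 fold change -0.53 ± 0.12 SE, edgeR adjusted p = 0.067), and passed with the block (adjusted p = 0.019), with scaling by library totals (0.025), with no filter (1.2e-04) and without white replicate 2 (0.039). Adjusted over the list alone, 3 of the 34 tested microRNAs were lower in white (miR166, miR159 and miR371) and 0 were higher. With the block, 4 microRNAs passed as lower over all tested rows (miR166, miR159, miR371 and miR164) and 1 as higher (miR167, adjusted p = 0.014). The call of miR166 was lost without red replicate 1 (edgeR adjusted p = 0.058), white replicate 1 (0.084) or white replicate 3 (0.107), and with scaling to the microRNA total (0.22). That total holds the reads of miR166 itself, so scaling to it shrinks the difference.

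Several families with lower means in white did not pass in the main edgeR test. miR171, which targets GRAS transcription factors of the HAM group, stood at 747.7 ± 266.2 CPM in red and 447.6 ± 54.6 CPM in white (edgeR adjusted p = 0.31). The near-identical miR170, with which it can share reads, had a log2 fold change of -0.83 ± 0.24 SE (adjusted p = 0.17). Red replicate 2 stood apart from the other red libraries for both, at 1521 reads of miR171 against 3604 and 2983, and 596 reads of miR170 against 1373 and 1062. Without it both passed (edgeR adjusted p = 0.0010 each), as they did with no filter on low counts (3.9e-05 for miR171 and 5.7e-05 for miR170). miR170 also passed with scaling by library totals (edgeR adjusted p = 0.036) and by DESeq2 (adjusted p = 0.048). miR164, which targets NAC genes of the CUC group, had a log2 fold change of -0.65 ± 0.21 SE (adjusted p = 0.17), and miR394 one of -0.84 ± 0.28 SE (adjusted p = 0.21). miR319, which targets TCP genes and resembles miR159 in sequence, had a log2 fold change of -0.83 ± 0.39 SE (adjusted p = 0.44, and 0.027 with no filter). With 1 library left out it ranged from -1.31 to -0.48. miR858, a regulator of MYB genes that include activators of the flavonoid pathway, stood at 1521 ± 454.9 CPM in red and 1341 ± 113.2 CPM in white (adjusted p = 0.78). Red replicate 2 was low for miR858 too, at 3426 reads against 6954 and 6071 in the other red libraries. With 1 library left out the log2 fold change of miR858 ranged from -0.41 to -0.053. miR396, the most abundant microRNA, stood at 17526 ± 1943 and 18539 ± 2120 CPM (adjusted p = 0.86), and the sign of its small difference turned with scaling by library totals.

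As a group, 15 of the 22 tested plant families had lower values in white and 7 higher, with a median log2 fold change of -0.28. Camera with the preset correlation placed them below the other rows (adjusted p = 0.0071 over 3 lists), and the call was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation). The limma function fry gave an adjusted p of 0.093 for a common direction. Unadjusted p-values of the plant families in the main fit were 0.0024 by camera with the preset correlation, 0.066 with an estimated one and 0.031 by fry. With the replicate number as a block they were 0.0067, 0.23 and 0.14. The 34 microRNA names together had a median log2 fold change of -0.18 and a camera p of 0.060, and the 12 other names a median of 0.20 and a camera p of 0.41. All microRNA names together made up 4.75% ± 0.24 of the reads in red and 3.75% ± 0.11 in white (SD, n = 3 each), with each red library above each white one (exact permutation p = 0.1, adjusted 0.2 over 4 library measures). The contig reads per microRNA read given above restate this share. Without the 3 most abundant contigs the share was 9.15% ± 0.34 in red and 6.90% ± 0.91 in white (exact permutation p = 0.1). The plant family list was written after the table was seen.

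**Figure D2:**
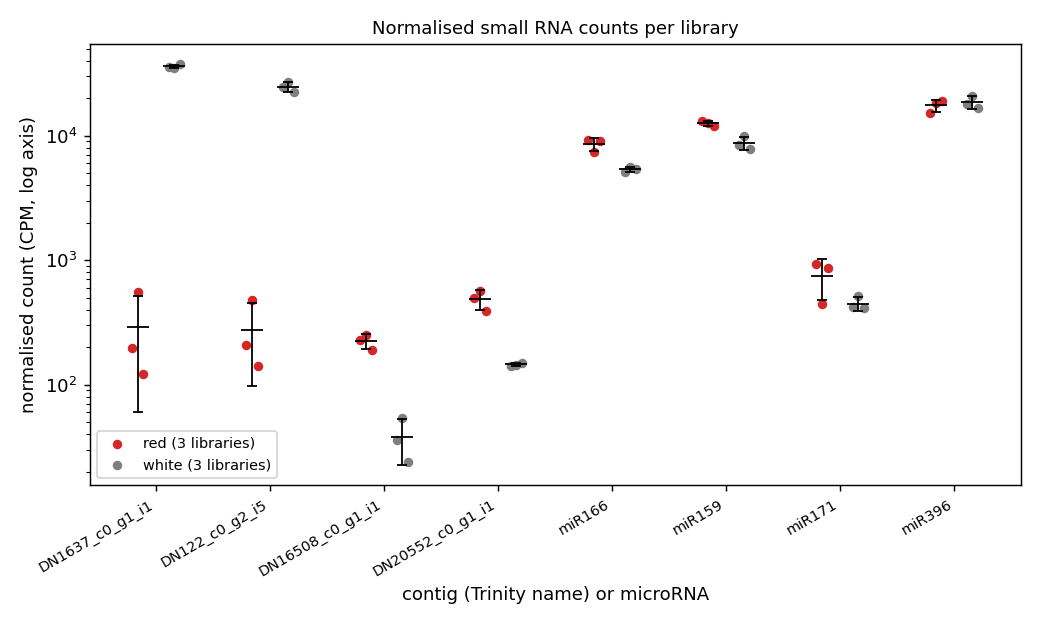
Normalised counts (CPM, log axis) of 4 contigs and 4 microRNAs in each of the 3 red and 3 white libraries, with horizontal bars for group means and error bars for 1 SD. The red and white libraries do not overlap for the 4 contigs, miR166 and miR159, and they overlap for miR171 and miR396.

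The contigs of the TRINITY_DN1364 cluster, the most abundant of all, differed between the parts by less than the spread between libraries. TRINITY_DN1364_c0_g1_i1 stood at 168609 ± 15379 CPM in red and 177189 ± 39833 CPM in white (edgeR adjusted p = 0.90), and TRINITY_DN1364_c0_g2_i2 had a log2 fold change of 0.09 ± 0.16 SE (edgeR adjusted p = 0.87). The 3 contigs of this cluster took 48.0% ± 1.8 of all reads in red and 45.1% ± 5.3 in white (SD, n = 3 each; exact permutation p = 0.4). The 1742 most abundant of the 6967 tested contigs held 20 of the 37 risen and 35 of the 36 fallen contigs.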

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

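The added alternatives (Trinity genes, microRNA rows, microRNA scaling, the most abundant contigs, the filter without red replicate 1, contig reads per microRNA read) and those of the microRNA share were chosen after seeing the data. The 74 changed rows became 154 with library totals (109 lower), 254 with no filter (126 higher, 128 lower), 118 with the stricter filter (71 higher), 338 with the replicate block (157 higher, 181 lower), 136 with scaling to the microRNA total (117 higher, 19 lower) and 45 with a 2-fold minimum (14 lower). DESeq2 called 109 rows, 60 of them higher in white, and left 3937 adjusted p-values undefined. A 2-fold minimum can only lower the count. The block can raise or lower it, and same-numbered libraries were correlated as given above. The causes of the changes other than that of the 2-fold minimum were not tested. Leaving out 1 library gave 35 to 176 changed rows, 19 to 76 higher and 16 to 100 lower. Of the 74 calls, 37 remained without red replicate 1, 71 without red replicate 2 and 31 without white replicate 3. Summed to Trinity genes, 62 genes passed. The share of rows higher in white was 34.7% with library totals, 32.3% on counts as deposited, 44.7% with no filter and 67.8% with microRNA scaling, and 48.4% to 51.4% with 1 library left out. The median log2 fold change of microRNA names ranged from -0.29 to 0.036 with 1 library left out. It turned positive without red replicate 2, where the camera p was 0.037 against 0.060 in the main fit. The direction camera gave there was not recorded. The difference in total counts (white minus red) of -56469 reads ranged from -160187 to 32047 with 1 library left out, turning without red replicate 1. It was -218527 reads with the 10 most abundant rows left out (exact permutation p = 0.1), which removes the 3 contigs with the largest rise in white and so lowers the white totals by construction. For the difference in total counts, which depends on sequencing depth, the exact paired sign-flip test of the replicate block gave p = 0.5. Contig reads per microRNA read, which restate the microRNA share, were higher in white by 5.60. Among named rows, 9 alternatives turned a sign, none of a called row: with library totals TRINITY_DN1364_c0_g1_i1 (-0.10), TRINITY_DN1364_c0_g2_i2 (-0.089) and miR396 (-0.086), and with 1 library left out the same 3 and miR156 (lowest -0.13, -0.11, -0.013 and -0.14, highest 0.18, 0.19, 0.15 and 0.46). The block ended the call of TRINITY_DN1637_c0_g1_i1, added miR159, miR164, miR167 and miR371 among the named rows and changed no other call of a named row. Over rows of all abundances, the simulation recovered 27.6% of 2-fold changes, so many changes of that size or smaller could be missed. Some were called, since 45 of the 74 calls remained at a 2-fold minimum. Contigs without reads in red replicate 1 were not analysed here, so contigs whose small RNAs occur in white tissue alone could be missing from the 37 rises. Alternatives listed for chalcone synthase, flavonoid, phased siRNA and size class results were not run, because contig names and read lengths were not analysed here.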

Other observations

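The tests of explanations in this part, other than the splits of the samples, were chosen after the results were seen. The other isoforms of TRINITY_DN122_c0_g2 went the opposite way to the isoform that rose 89.5-fold. Of its 6 tested isoforms, 1 rose and 3 fell by the edgeR test, and the reads in all isoforms but the risen one numbered 7495 ± 1051 in red and 4303 ± 950 in white (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). MicroRNAs that target the silencing machinery did not pass over all tested rows. miR168, which targets AGO1, had a log2 fold change of -0.32 ± 0.13 SE (edgeR adjusted p = 0.33). miR403, which targets AGO2, had one of -0.41 ± 0.16 SE (adjusted p = 0.29), and miR162, which targets DCL1, one of 0.28 ± 0.16 SE (adjusted p = 0.53). With 1 library left out miR403 ranged from -0.55 to -0.23 and miR162 from 0.11 to 0.42. miR390, the trigger of TAS3 siRNAs, had at most 5 reads in any library and was not tested.

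The real grouping gave 74 changed rows (37 higher, 37 lower), and among the 10 splits of the 6 libraries 3 against 3 only 1, the real one, gave as many. The highest other split gave 1 changed row, 1 higher and 0 lower. With 10 splits a share under 0.05 cannot be reached.

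The first pattern is the set of 10 contigs at least 8-fold higher in white. Over 4 scalings of the libraries the lowest log2 ratio of group means was 2.82. The contigs were picked for a rise of at least 8-fold. Scaling moved the median log2 fold change of all rows only to -0.17 with library totals and 0.18 with the microRNA total. The outcome was thus fixed by the choice of contigs, and 2.82 is given as a size and not as a test. A move of reads between isoforms of a Trinity gene is argued against as the whole cause for TRINITY_DN122_c0_g2. Its summed isoforms had a log2 fold change of 3.42, against 6.48 for the isoform that rose. Among the 8 Trinity genes of these contigs, isoforms summed and the row-level TMM scaling kept, the lowest log2 ratio of group means was 2.64. In the edgeR fit of summed isoforms the lowest log2 fold change was 2.60. For several of these genes the sum nearly equalled the picked contigs, so it could not fall and decides nothing there. Reads shared between Trinity genes were not covered. White tissue carried into the red samples stays open as a source of the red reads. The ratio of TRINITY_DN122_c0_g2_i5 to both TRINITY_DN1637_c0_g1 isoforms was higher in red than in white by 0.133, beyond 2 SD of the libraries (0.081). This cannot decide, because reads shared with the other TRINITY_DN122_c0_g2 isoforms, more numerous in red, could raise the ratio there. The contigs of this ratio also moved together in red, highest in replicate 2 and lowest in replicate 3, as carry-over would give. The other contigs of the set were not covered by this ratio. Their log2 fold changes ran from 3.00 to 3.98, against 6.48 to 6.96 for the contigs of the ratio. Carry-over as the whole source would give all contigs a like ratio of red to white reads. This argues against carry-over as the whole source for those other contigs. Several were near the floor in red, but the most abundant stood at 18.8 ± 5.3 CPM in red and 195.0 ± 48.4 CPM in white. For the contigs of the ratio, a part or all of the red reads may be carry-over. A difference between the red and white tissue stays open as the hypothesis the design gives. Whether these contigs are flavonoid genes was not analysed here.

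The second pattern is the lower microRNA share of reads in white. Dilution by the risen contigs is argued against as the whole cause, because without them the lowest red library still exceeded the highest white one by 0.267 percentage points. It may account for part, since the means were 4.79% in red and 4.20% in white without them, against 4.75% and 3.75% with them. Whether miR159 and miR166 alone make the pattern stays open: without them the groups overlapped (gap -0.179 points), but they were picked because they were lower in white, so the overlap decides nothing.

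The third pattern is a count of 694 for miR-27 and 77 for bantam in red replicate 1, against at most 21 and 5 in the other libraries. Both are animal microRNA names, and with names of at most 6 characters miR-27 could also hold longer family numbers. The selection of rows with a read in red replicate 1 is argued against, since 0 of 14823 contig rows with at most 5 reads elsewhere, as bantam had, reached 77 reads there (the highest was 11), and 0 of 40687 with at most 52 reads elsewhere, as miR-27 had, reached 694 (the highest was 42). Insect RNA in that library cannot be told apart from other sources: other insect family names had 55 reads there and 59 in the highest other library, a difference of -4 against a counting error of 21.4 (2 SD), and plant reads under those names would hide a small share. The design gives no biological explanation to test.

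Single libraries also stood apart for other microRNA names: miR647 had 7093 reads in white replicate 2 and between 714 and 1308 in the other libraries, and miR-81 had 175 reads in white replicate 1 and between 12 and 41 in the others.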
